A study of Homo sapiens with 12 samples.

How the data were processed

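RNA was measured in 12 libraries from HepG2 cells treated for 12 h with 10 µM sorafenib or vehicle, with 3 libraries for each of the 4 combinations of treatment and gradient fraction. Per the labels' protocols, light and polysome fractions of each gradient were pooled separately, and the series is described as ribosome profiling, although the protocol text describes libraries from the RNA of pooled fractions. The values are whole-number counts per gene that the authors deposited, not normalized. The genome build was GRCh38.p12, per the submitters' processing notes; the aligner, counting tool, annotation and use of strand are not given in the sources used here.

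The table has 57353 rows. Gene symbols were looked up in RefSeq genes of assembly GRCh38.p14: 37257 matched, 37 were mitochondrial and 20059 did not match. Since builds differ, no coordinates are given. Of the tested rows, 14 have counts identical to another tested row, and genes with near-identical copies or overlapping neighbours are uncertain, as are antisense genes.

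Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, DESeq2 1.42.0): filterByExpr on the 4 groups left 14955 genes, and the 42398 untested rows held at most 4.54% of a library's counts. TMM factors ranged from 0.637 to 1.41, with sorafenib light-fraction library 2 as the automatic reference. The quasi-likelihood test used all 12 libraries without a block, Benjamini-Hochberg adjusted p under 0.05; the common biological coefficient of variation was 0.245. SE is the absolute log2 fold change over the square root of F. Of 33 gene lists fixed before the data were examined, 32 had at least 5 tested members and were tested with camera at a correlation of 0.01, adjusted over the lists. Shares were compared by exact permutation.

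Named genes followed a rule written before the data were examined: the 5 largest rises and falls with a mean log2 CPM of at least 3 and non-overlapping replicates, 4 members by p of each called list or 2 of others, and 14 fixed genes. From the genes this rule allows, a part was chosen for length after their values were seen. Replicates are separate cultures as far as the labels call the experiments triplicate; where they are not, p-values measure only the spread between these libraries. Replicate pairs of each group differed beyond sampling noise (chi-square per degree of freedom 9.99 to 51.1).

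Libraries of the same number and treatment are fractions of 1 culture, per the labels. Their deviations from the group means correlated at 0.12, -0.09, 0.28 in vehicle and 0.04, 0.03, 0.03 in sorafenib cultures. In the labels, sorafenib polysome library 3 carries the same sample index as vehicle light-fraction library 1, whereas the index of each other library follows its number. Whether it was sequenced in another run is not given in the sources used here, and a run that holds 1 library cannot be told apart from that library. Alternatives covered scaling, filters, tools, blocks, gene sets and leaving out each library or culture. After seeing the data, 3 kinds were added: thinning all libraries to the smallest total, leaving out both shallow sorafenib light-fraction libraries, and TMM with each of the 11 other libraries as reference.

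The methods were tested on simulated data of 14955 genes with the real depths and 1 estimated dispersion per gene, shared by the 4 groups. The real sorafenib light-fraction replicates were less alike (r = 0.74 to 0.90) than those of other groups (0.94 to 0.98). The rates for comparisons with that group may therefore be too favourable. Each gene started from its mean over all 12 libraries in every group, so the real differences between fractions and treatments were absent. The rates rest on 66 or 67 changed genes per fold, all well counted. Far fewer genes changed than the real fits called, so the rates need not hold there or for low-count genes. For the polysome comparison, 4-fold changes were recovered in 98.5%, 2-fold in 38.8% and 1.5-fold in 11.9% of genes. For the light fraction it was 95.5%, 31.3% and 0%, and for the interaction 81.8%, 1.49% and 1.49%. In the interaction 8 unchanged genes were called, 11.8% of its calls. Totals of 511065 to 13336689 counts per library set the precision, and low-count genes in the sorafenib light fraction are measured least well. Figures were drawn with matplotlib 3.10.9.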

Results

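HepG2, a human liver cancer cell line, was exposed to 10 µM sorafenib, a multikinase inhibitor used against hepatocellular carcinoma, or to its vehicle DMSO for 12 h. Lysates made with cycloheximide, which arrests ribosomes on mRNA, were separated on sucrose gradients. RNA was sequenced from a light pool (F1: low-molecular complexes, free subunits and single ribosomes) and a polysome pool (F2). The deposited table holds gene counts for 12 libraries from 6 cultures, 3 per treatment, each giving 1 library per fraction. Total counts were 9888231, 11955977 and 7387602 in the vehicle light fraction and 2060384, 511065 and 4989312 in the sorafenib light fraction. They were 10584699, 4769383 and 9583095 in the vehicle polysome fraction and 10011614, 13336689 and 10044378 in the sorafenib polysome fraction. After thinning to 500000 counts, sorafenib light-fraction library 2 held 25461 detected genes and library 1 held 16711, against 13168 to 14576 in each other library. Library 2 of that group, the shallowest, was also the reference that TMM scaling chose. Its TMM-scaled log2 CPM correlated with libraries 1 and 3 of its group at 0.76 and 0.74, and those 2 at 0.90 with each other. Replicates of the other groups correlated at 0.94 to 0.98. Sorafenib light-fraction library 3 correlated at 0.91 with each sorafenib polysome library, so the replicates of the sorafenib light fraction were less alike than those of other groups. Since each library was scaled to its own depth, all changes are relative to the other genes and none is a change in the amount of RNA. No library of unfractionated RNA is among the 12, so a change on polysomes alone cannot be told apart from a change in the level of the mRNA.

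**Figure D1:**
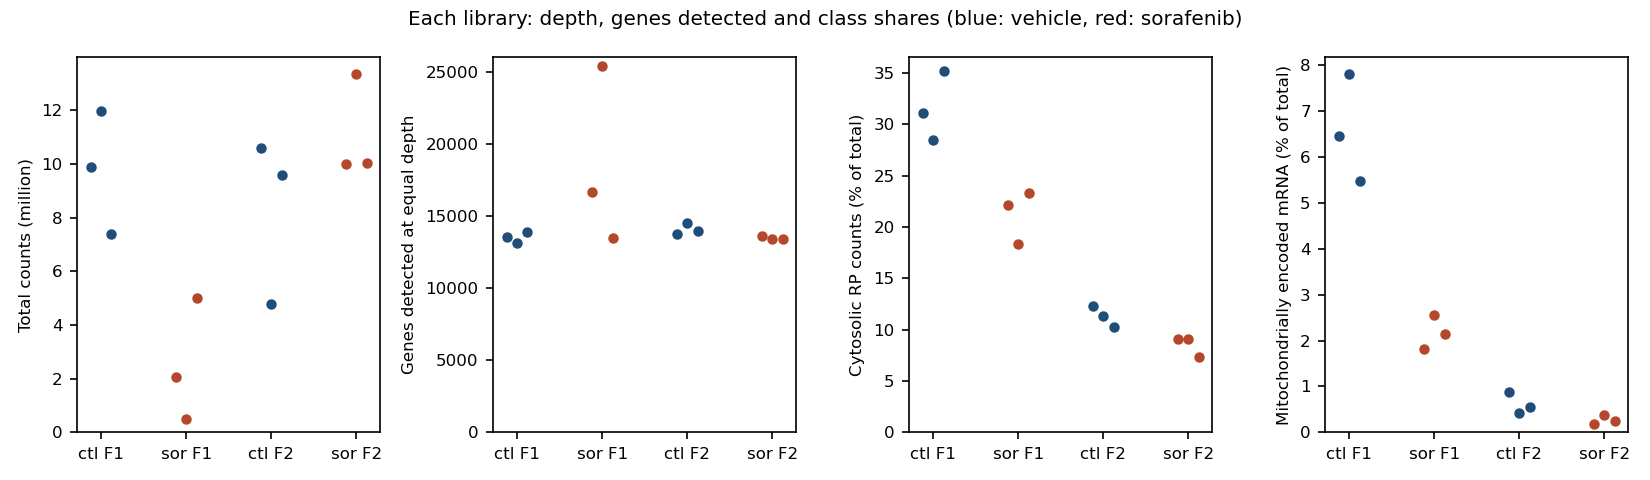
Each point is 1 library, in groups of 3 by treatment and fraction (blue, vehicle; red, sorafenib), and the panels show total counts, genes detected after thinning to equal depth, and the percent of counts from cytosolic ribosomal protein genes and from mitochondrially encoded mRNAs. Sorafenib light-fraction library 2 stands apart at 25461 genes.

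Cytosolic ribosomal protein genes, which encode the ribosome itself, took a smaller share of the counts after sorafenib. In the light fraction their share was 31.6% ± 3.35 with vehicle and 21.2% ± 2.6 with sorafenib (SD, n = 3 each). In the polysome fraction it was 11.3% ± 1.05 with vehicle and 8.48% ± 1.01 with sorafenib (SD, n = 3 each). Mitochondrially encoded mRNAs, which encode respiratory chain and ATP synthase subunits, went from 6.57% ± 1.17 to 2.17% ± 0.368 of light-fraction counts (SD, n = 3 each). Their share of polysome counts was 0.62% ± 0.238 with vehicle and 0.266% ± 0.0942 with sorafenib (SD, n = 3 each). In each of these 4 contrasts the groups did not overlap, as happens by chance in 10% of cases, and the exact permutation test (both sides) gave p = 0.1, the smallest that 3 against 3 allows. A fixed set of the 10 genes most abundant over all 12 libraries, led by MT-RNR2 and EEF1A1 and so not the top genes of each group, took 21.7% of light-fraction counts with vehicle and 16% with sorafenib (exact permutation p = 0.1). Of polysome counts the same set took 3.92% and 4.57% (exact permutation p = 0.3).

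The first comparison asked which mRNAs changed in the polysome fraction under sorafenib. Genes for enzymes that charge tRNAs, targets of the stress transcription factor ATF4, secreted liver proteins and glycolytic enzymes mostly rose, while genes for nuclear-encoded respiratory chain subunits and mitochondrial ribosomal proteins mostly fell. SLC44A2, a choline transporter, rose by 4.04 ± 0.36 on the log2 scale (SE, n = 3 per group), CCN1, a secreted matricellular protein, by 4.01, and CES1, a liver carboxylesterase, by 3.85. SLC25A25 (3.85), a mitochondrial carrier, and ELF3 (3.69), an epithelial transcription factor, also rose. The mitochondrial tRNAs MT-TT (-4.50 ± 0.58), MT-TP (-3.63) and MT-TE (-3.58) fell, next to EPOP (-3.62) and ETAA1 (-3.45). Of 14955 genes tested, 3130 rose and 4306 fell by the edgeR quasi-likelihood test, 2178 and 2976 of them by at least 2-fold. The median of all genes was -0.26, and 42.1% of the calls were rises; with TMM computed within each fraction the median was -0.03, 3917 genes rose and 3143 fell (55.5% rises), and over the 11 other TMM references rises made up 44.6% to 56.9%. Falls numbered 2663 without vehicle light-fraction library 1, 2577 without vehicle light-fraction library 2, 2836 without vehicle light-fraction library 3; without both shallow sorafenib light-fraction libraries 4365 genes rose and 3463 fell. Light-fraction libraries are not part of this contrast, but each fit filtered, scaled and estimated the spread anew. Without vehicle light-fraction libraries 1, 2 and 3 in turn, 16260, 16312 and 16268 genes were tested. Without sorafenib polysome library 3, whose sequencing run is uncertain, 2442 rose and 3156 fell. With both libraries of 1 culture left out, falls numbered 2322 without vehicle culture 1 and 2514 without vehicle culture 3. Other settings also changed how many genes were tested. Without a low-count filter 3904 of 45832 genes rose and 1663 fell. With protein-coding genes only 3300 of 11828 rose and 2742 fell. With all libraries thinned to the smallest total 1715 of 7670 rose and 1715 fell.

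Of 20 tRNA synthetase genes tested, 20 rose, 0 fell and 0 did not pass the test (20 and 0 adjusted over the list alone). The synthetases had a median of 1.45, with a camera adjusted p = 1.26e-10, and adjusted p = 0.188 with an estimated correlation. AARS (2.64), NARS (2.27) and VARS (2.07), which charge alanine, asparagine and valine tRNAs, were among them. Of 26 ATF4 and integrated stress response targets tested, 20 rose, 0 fell and 6 did not pass the test (21 and 0 adjusted over the list alone). The ATF4 targets had a median of 1.47, with a camera adjusted p = 2.02e-08, and adjusted p = 0.314 with an estimated correlation. PHGDH, the first enzyme of serine synthesis, rose by 2.89 ± 0.26 (SE, edgeR adjusted p = 5.02e-07), from 25.9 ± 6.83 to 193 ± 25.1 TMM-scaled CPM (SD, n = 3 each). Mitochondrial PEP carboxykinase PCK2 (2.83), the amino acid transporter chain SLC3A2 (3.47), the eIF2 phosphatase subunit PPP1R15A (2.48) and the stress transcription factor DDIT3 (2.23) rose too. ATF4 itself had a log2 fold change of -0.20 (adjusted p = 0.574), whose sign depended on the scaling. Of 26 unfolded protein response genes tested, 13 rose, 6 fell and 7 did not pass the test (13 and 6 adjusted over the list alone). Unfolded protein response genes had a median of 0.64, with a camera adjusted p = 0.00661, and adjusted p = 0.401 with an estimated correlation. The chaperones PDIA4 (2.28), PDIA3 (2.30) and HSPA5 (2.19) were among those that rose.

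Of 28 secreted hepatocyte protein genes tested, 21 rose, 2 fell and 5 did not pass the test (21 and 2 adjusted over the list alone). Secreted proteins had a median of 1.89, with a camera adjusted p = 2.39e-10, and adjusted p = 0.268 with an estimated correlation. Prothrombin (gene F2, 2.52), the fibrinogen chain FGA (2.89), the hyaluronan-binding ITIH2 (2.98) and albumin (ALB, 2.31) rose. Of 18 glycolysis genes tested, 13 rose, 0 fell and 5 did not pass the test (13 and 0 adjusted over the list alone). Glycolysis genes had a median of 1.43, with a camera adjusted p = 3.93e-06, and adjusted p = 0.268 with an estimated correlation. The enzymes PFKL (1.91), ENO2 (2.18) and PKM (2.12) were examples. Of 12 fatty acid synthesis genes tested, 8 rose, 0 fell and 4 did not pass the test (8 and 1 adjusted over the list alone). Lipid synthesis genes had a median of 0.98, with a camera adjusted p = 0.00109, and adjusted p = 0.327 with an estimated correlation. Among them were the regulator SREBF1 (1.92), ATP citrate lyase ACLY (2.08) and fatty acid synthase FASN (2.42). Of 14 fatty acid oxidation genes tested, 7 rose, 0 fell and 7 did not pass the test (7 and 0 adjusted over the list alone). Oxidation genes had a median of 0.78, with a camera adjusted p = 4.74e-04, and adjusted p = 0.188 with an estimated correlation. HADHA (2.24) and ACADVL (1.78), enzymes of long-chain oxidation, rose.

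Of 29 mitosis genes tested, 22 rose, 4 fell and 3 did not pass the test (23 and 4 adjusted over the list alone). Mitosis genes had a median of 1.15, with a camera adjusted p = 5.52e-07, and adjusted p = 0.188 with an estimated correlation. The spindle factor TPX2 (2.08), topoisomerase TOP2A (2.40) and the checkpoint kinase BUB1B (1.79) rose. Of 28 S phase and DNA replication genes tested, 14 rose, 8 fell and 6 did not pass the test (14 and 8 adjusted over the list alone). Replication genes had a median of 0.44, with a camera adjusted p = 0.002, and adjusted p = 0.327 with an estimated correlation. The helicase subunit MCM2 (2.55) and the ribonucleotide reductase subunit RRM1 (2.19) rose. Of 38 ribosome biogenesis genes tested, 27 rose, 3 fell and 8 did not pass the test (27 and 3 adjusted over the list alone). Biogenesis factors had a median of 0.92, with a camera adjusted p = 7.19e-08, and adjusted p = 0.188 with an estimated correlation. NOC2L (2.40), the RNA polymerase I factor RRN3 (2.12), RRP12 (1.89) and nucleolin (NCL, 2.30) rose. mRNAs with a 5' terminal oligopyrimidine tract (TOP) encode ribosomal proteins and translation factors. Of 26 translation factors and other TOP mRNAs tested, 8 rose, 1 fell and 17 did not pass the test (8 and 1 adjusted over the list alone). TOP mRNAs had a median of 0.43, with a camera adjusted p = 0.0169, and adjusted p = 0.556 with an estimated correlation. EIF3A (1.63), EEF2 (1.43), HNRNPA1 (1.31) and EEF1A1 (1.07) rose. Of 79 cytosolic ribosomal protein genes tested, 2 rose, 31 fell and 46 did not pass the test (2 and 24 adjusted over the list alone). Cytosolic ribosomal proteins had a median of -0.66, with a camera adjusted p = 0.00366, and adjusted p = 0.682 with an estimated correlation. RPS26 (-1.97), RPL38 (-1.54) and RPL35A (-1.32) fell, while RPLP0 (-0.10) and RPS6 (-0.21) did not pass the test and had signs that depended on the scaling.

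Of 77 nuclear-encoded respiratory chain and ATP synthase genes tested, 9 rose, 59 fell and 9 did not pass the test (10 and 61 adjusted over the list alone). Respiratory chain genes had a median of -1.20, with a camera adjusted p = 1.56e-06, and adjusted p = 0.327 with an estimated correlation. The complex I subunits NDUFA3 (-1.89) and NDUFB1 (-2.12) fell, whereas the complex II flavoprotein SDHA (2.52) rose. Of 76 mitochondrial ribosomal protein genes tested, 6 rose, 46 fell and 24 did not pass the test (6 and 49 adjusted over the list alone). Mitochondrial ribosomal proteins had a median of -0.77, with a camera adjusted p = 3.65e-05, and adjusted p = 0.379 with an estimated correlation. MRPL36 (-2.18) and MRPS17 (-1.57) were examples. Of 13 mitochondrially encoded mRNAs tested, 0 rose, 12 fell and 1 did not pass the test (0 and 13 adjusted over the list alone). These mitochondrial mRNAs had a median of -1.94, with a camera adjusted p = 8.54e-05, and adjusted p = 0.314 with an estimated correlation. The complex I subunits MT-ND5 (-2.59) and MT-ND2 (-2.85) fell. Of 12 mitochondrial chaperone and protease genes tested, 7 rose, 2 fell and 3 did not pass the test (7 and 2 adjusted over the list alone). Mitochondrial chaperones had a median of 0.96, with a camera adjusted p = 0.00566, and adjusted p = 0.268 with an estimated correlation. The mitochondrial HSP70 gene HSPA9 rose (2.49) and the co-chaperonin gene HSPE1 fell (-2.06). RAF kinases, upstream of MEK and ERK, are targets of sorafenib. Of 21 RAF-MEK-ERK output genes tested, 4 rose, 4 fell and 13 did not pass the test (3 and 4 adjusted over the list alone). ERK output genes did not pass as a list (camera adjusted p = 0.867). DUSP6, an ERK phosphatase, was at -0.87 (adjusted p = 0.083), the ETS factor ETV4 fell (-1.80), and the transcription factors JUN (3.41) and MYC (1.56) rose. Of the 32 lists, 20 passed at the preset correlation and 0 with an estimated one.

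**Figure D2:**
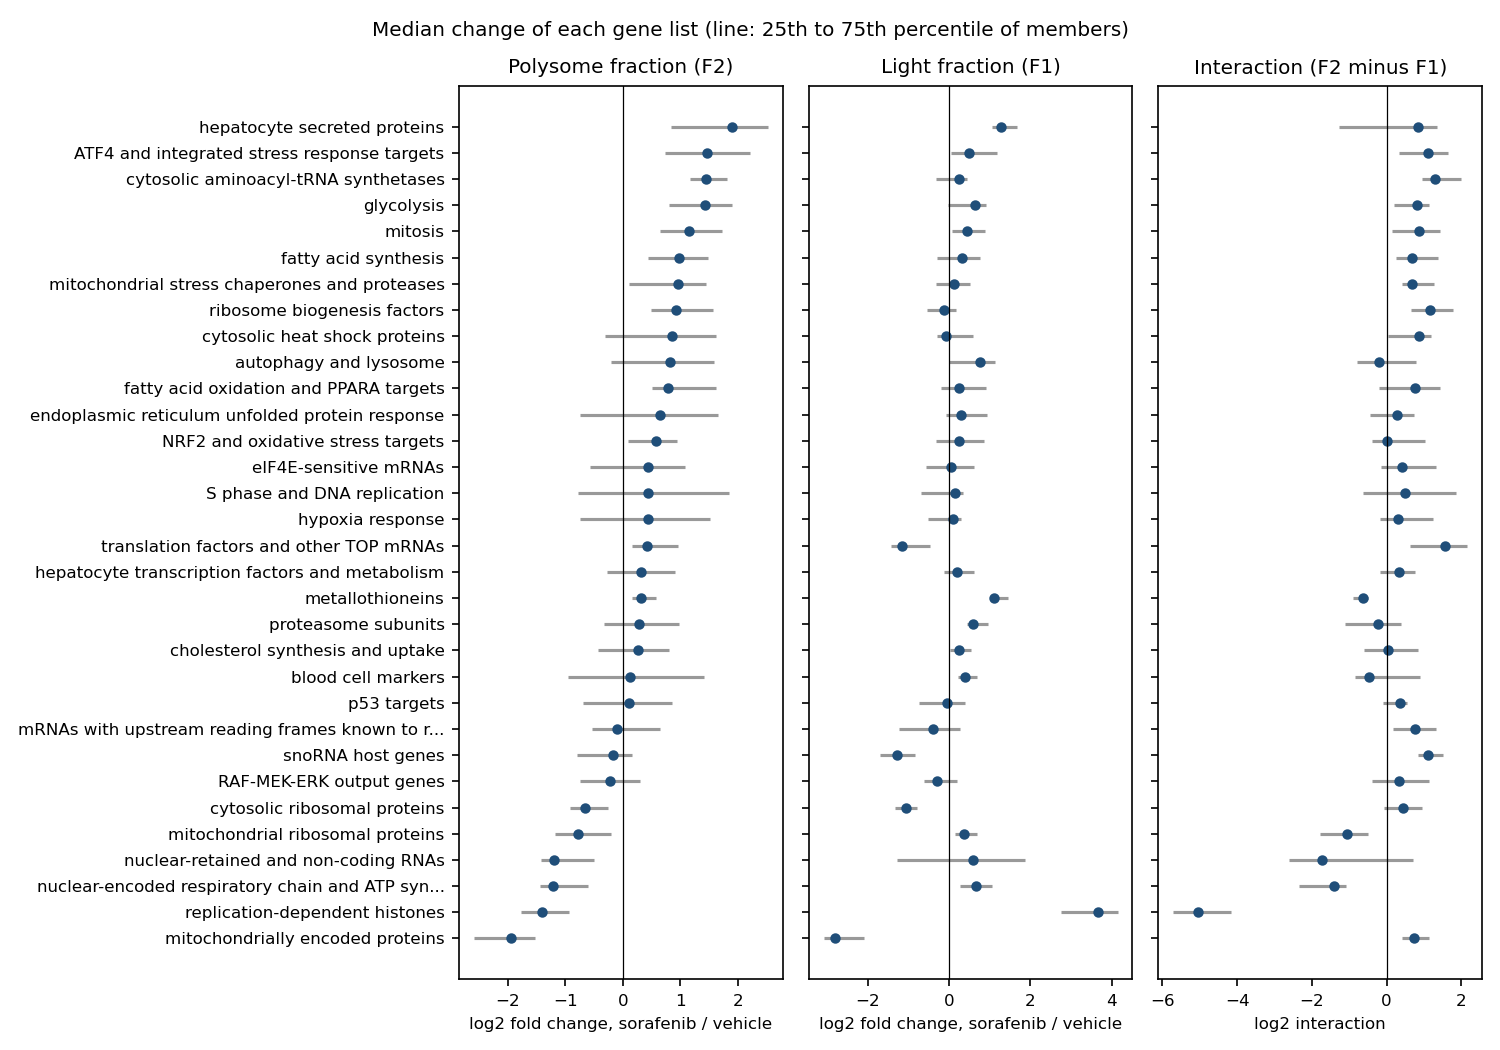
Each row is 1 of the 32 gene lists with at least 5 tested members; the point is the median log2 change of its members and the grey line spans their 25th to 75th percentile, for sorafenib against vehicle in the polysome fraction, in the light fraction, and for the difference between the fractions. Histones sit at 3.67 in the light fraction and at -1.40 in the polysome fraction, where the list did not pass (camera adjusted p = 0.0668).

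The second comparison asked the same of the light fraction. Genes for replication-dependent histones and secreted liver proteins mostly rose there, as did 38 of 77 respiratory chain genes, and those for cytosolic ribosomal proteins, other TOP mRNAs, snoRNA hosts and mitochondrially encoded mRNAs mostly fell. The 5S rRNA pseudogene RNA5SP202, for which sharing of reads with other genes was not tested, rose by 5.82. The linker histone gene HIST1H1E rose by 4.23 ± 0.92 (SE, n = 3 per group), SLC44A2 by 3.59 and the skeletal actin gene ACTA1 by 3.07. MT-TT fell by 4.22, EPOP by 3.64 and the long non-coding RNA NORAD by 3.63. By the edgeR test 1752 genes rose and 2648 fell. Rises made up 39.8% of the calls at a median of -0.12 over all genes. Over the 11 other TMM references rises made up 45.3% to 49.7%, with 2144 to 2383 falls and medians of -0.0542 to -0.000629. The main values lie outside these ranges, so most of the excess of falls depended on the reference. With library totals as the only scale the median was 0.31, 3650 genes rose and 1316 fell (73.5% rises). Falls numbered 1748 without vehicle light-fraction library 1, 1747 without vehicle light-fraction library 2, 1412 without sorafenib light-fraction library 1; without both shallow libraries, which leaves 1 sorafenib library assumed to vary like the other groups, 1751 genes rose and 1333 fell. With both libraries of 1 culture left out, rises numbered 1021 without vehicle culture 2 and 909 without sorafenib culture 1, and falls numbered 1579 without sorafenib culture 1. The DESeq2 Wald test gave 2718 rises and 2312 falls. It ran on 45832 genes without the low-count filter and with its own scaling, so tool, filter and scaling changed together. With protein-coding genes only 1782 of 11828 rose and 1728 fell. With all libraries thinned to the smallest total 844 of 7670 rose and 988 fell.

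Replication-dependent histone mRNAs lack a poly(A) tail. Of 36 replication-dependent histone genes tested, 34 rose, 0 fell and 2 did not pass the test (35 and 0 adjusted over the list alone). Histones had a median of 3.67, with a camera adjusted p = 9.35e-22, and adjusted p = 0.285 with an estimated correlation. HIST1H3H, a histone H3 gene, went from 8.38 ± 0.234 to 61.4 ± 33.8 TMM-scaled CPM (SD, n = 3 each), a rise of 2.75, and the linker histone gene HIST1H1C rose by 2.57. Some members had few counts, such as HIST1H2BC (5.23) at a mean log2 CPM of 1.37. In the polysome fraction 9 of the 36 fell (4 adjusted over the list alone) and 27 did not pass the test. In the light-fraction libraries 6 other RNAs without a poly(A) tail had a median of 1.92, 1 of them passing the test, and without both shallow libraries the histone median was 3.01. Of 28 secreted hepatocyte protein genes tested, 23 rose, 0 fell and 5 did not pass the test (23 and 1 adjusted over the list alone). Secreted proteins had a median of 1.29, with a camera adjusted p = 6.90e-15, and adjusted p = 0.285 with an estimated correlation. Haptoglobin (HP, 2.96), the apolipoproteins APOA1 (2.89) and APOE (2.15), AMBP (1.92) and ALB (1.50) rose. Of 77 nuclear-encoded respiratory chain and ATP synthase genes tested, 38 rose, 0 fell and 39 did not pass the test (41 and 0 adjusted over the list alone). Respiratory chain genes had a median of 0.66, with a camera adjusted p = 7.97e-11, and adjusted p = 0.314 with an estimated correlation. NDUFA9 (1.53) and NDUFB10 (1.51), both of complex I, rose. Of 76 mitochondrial ribosomal protein genes tested, 20 rose, 3 fell and 53 did not pass the test (20 and 3 adjusted over the list alone). Mitochondrial ribosomal proteins had a median of 0.38, with a camera adjusted p = 2.31e-05, and adjusted p = 0.495 with an estimated correlation. MRPL54 (1.98) and MRPL27 (1.91) were examples.

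Of 32 proteasome subunit genes tested, 15 rose, 0 fell and 17 did not pass the test (17 and 0 adjusted over the list alone). Proteasome genes had a median of 0.58, with a camera adjusted p = 1.66e-07, and adjusted p = 0.314 with an estimated correlation. PSMD11 (1.38) and PSMB3 (1.54) rose. Of 28 autophagy and lysosome genes tested, 13 rose, 1 fell and 14 did not pass the test (14 and 1 adjusted over the list alone). Lysosomal genes had a median of 0.75, with a camera adjusted p = 1.67e-05, and adjusted p = 0.285 with an estimated correlation. The cathepsins CTSL (1.91) and CTSB (2.54), lysosomal proteases, rose. Of 26 ATF4 and integrated stress response targets tested, 10 rose, 1 fell and 15 did not pass the test (10 and 2 adjusted over the list alone). The ATF4 targets had a median of 0.49, with a camera adjusted p = 0.00564, and adjusted p = 0.586 with an estimated correlation. The stress protein gene NUPR1 (2.63) and the serine synthesis genes PSAT1 (1.73) and PHGDH (1.33) rose, while ATF4 fell (-1.94). DDIT3 (0.29), HSPA5 (0.57) and MYC (0.10) did not pass the test. Of 26 unfolded protein response genes 8 rose, among them PDIA3 (1.78) and PDIA4 (1.41), 1 fell and 17 did not pass (camera adjusted p = 0.00868). Of 18 glycolysis genes 7 rose, 0 fell and 11 did not pass (camera adjusted p = 0.00968). Neither list passed with an estimated correlation.

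Of 79 cytosolic ribosomal protein genes tested, 0 rose, 55 fell and 24 did not pass the test (0 and 63 adjusted over the list alone). Cytosolic ribosomal proteins had a median of -1.06, with a camera adjusted p = 1.92e-14, and adjusted p = 0.434 with an estimated correlation. RPLP0 (-1.66), RPLP1 (-1.81) and RPS6 (-1.13) fell. Of 26 translation factors and other TOP mRNAs tested, 0 rose, 17 fell and 9 did not pass the test (0 and 17 adjusted over the list alone). TOP mRNAs had a median of -1.17, with a camera adjusted p = 5.17e-08, and adjusted p = 0.314 with an estimated correlation. The poly(A)-binding protein gene PABPC1 (-1.91), EIF4B (-1.97), EEF1A1 (-1.11) and EEF2 (-1.23) fell. Of 17 snoRNA host genes tested, 0 rose, 11 fell and 6 did not pass the test (0 and 14 adjusted over the list alone). Host genes had a median of -1.28, with a camera adjusted p = 1.21e-07, and adjusted p = 0.33 with an estimated correlation. SNHG3 (-2.45) and SNHG16 (-1.73), and NOP56 (-3.27), a nucleolar protein gene with snoRNAs in its introns, fell. Of 13 mitochondrially encoded mRNAs tested, 0 rose, 13 fell and 0 did not pass the test (0 and 13 adjusted over the list alone). These mitochondrial mRNAs had a median of -2.81, with a camera adjusted p = 4.55e-13, and adjusted p = 0.285 with an estimated correlation. MT-ND1 (-3.96) and MT-ND2 (-3.57), of complex I, fell, and without both shallow libraries the median of these mRNAs was -2.15. Of 21 RAF-MEK-ERK output genes tested, 1 rose, 3 fell and 17 did not pass the test (1 and 3 adjusted over the list alone). ERK output genes did not pass as a list (camera adjusted p = 0.482). DUSP6 (-2.11), SPRY4 (-2.09) and IER3 (-1.26), each induced by ERK signalling, fell. Of the lists, 16 passed at the preset correlation and 0 with an estimated one.

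Across 14955 genes, which are not independent replicates, sorafenib effects in the light and polysome fractions correlated at Pearson r = 0.36 and Spearman rho = 0.36. Pearson r was 0.24 without vehicle light-fraction library 1, 0.22 without vehicle light-fraction library 3, 0.19 without sorafenib light-fraction library 3, 0.19 without vehicle polysome library 1, 0.21 without sorafenib polysome library 1, 0.26 without sorafenib polysome library 3. Of 2610 genes called in both fractions, 79.2% moved the same way. Of these 686 rose in both and 1380 fell in both, where independent calls would give 367 and 762. Both fractions came from the same cultures, so their calls are not independent and the excess does not measure the drug's effect alone.

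The third comparison tested whether the sorafenib effect differed between the fractions, as polysome change minus light-fraction change. Genes for respiratory chain subunits, mitochondrial ribosomal proteins and histones mostly had negative values, and those for translation factors, ribosome biogenesis and tRNA synthetases positive ones. NOP56 was at 3.79 ± 0.39 (SE, n = 3 per group), the actin nucleator DIAPH1 at 3.65, the collagen COL18A1 at 3.51 and the myosin chaperone UNC45A at 3.41. FTLP3 (4.38) is a ferritin pseudogene, and PTMAP5 (-4.54) and MIR1244-1 (-3.77) share sequence with PTMA. Reads of the parent ferritin gene and of PTMA cannot be told from theirs. HIST1H3H (-4.07), the cobalamin enzyme MMAB (-3.64) and parathymosin (PTMS, -3.62) were negative too. The edgeR interaction was positive for 1921 genes and negative for 1607. Positive values made up 54.5% of the calls; with TMM within each fraction 2335 were positive and 1282 negative (64.6% positive), and with library totals alone 1210 and 2390 (33.6%), at medians of 0.17 and -0.26. Negative calls numbered 871 without vehicle light-fraction library 1, 813 without vehicle light-fraction library 2, 843 without sorafenib light-fraction library 1, 1033 without sorafenib polysome library 3; without both shallow libraries 1554 genes were positive and 1171 negative. With both libraries of 1 culture left out, positive calls numbered 1136 without vehicle culture 2 and 898 without sorafenib culture 1, and negative calls numbered 884 without vehicle culture 1, 815 without vehicle culture 2, 997 without vehicle culture 3 and 701 without sorafenib culture 1. Without a low-count filter 2822 of 45832 genes were positive and 663 negative. With all libraries thinned to the smallest total 839 of 7670 were positive and 895 negative.

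Of 77 nuclear-encoded respiratory chain and ATP synthase genes tested, 5 had a positive interaction, 56 a negative one and 16 did not pass the test (6 and 63 adjusted over the list alone). Respiratory chain genes had a median of -1.41, with a camera adjusted p = 9.87e-25, and adjusted p = 0.155 with an estimated correlation. NDUFA11, a complex I subunit, went from 233 ± 27.8 to 640 ± 161 TMM-scaled CPM in the light fraction and from 681 ± 176 to 175 ± 9.45 in the polysome fraction (SD, n = 3 each). Its interaction was -3.41 ± 0.38 (SE, edgeR adjusted p = 3.24e-05), with NDUFA13 at -3.37 and NDUFA2 at -2.99. Of 76 mitochondrial ribosomal protein genes tested, 2 had a positive interaction, 39 a negative one and 35 did not pass the test (2 and 46 adjusted over the list alone). Mitochondrial ribosomal proteins had a median of -1.06, with a camera adjusted p = 5.24e-15, and adjusted p = 0.238 with an estimated correlation. MRPL54 (-3.38) and MRPL36 (-2.45) were examples. Of 36 replication-dependent histone genes tested, 0 had a positive interaction, 34 a negative one and 2 did not pass the test (0 and 35 adjusted over the list alone). Histones had a median of -5.05, with a camera adjusted p = 3.58e-22, and adjusted p = 0.238 with an estimated correlation. HIST1H2BC (-6.29, at a mean log2 CPM of only 1.37) and HIST1H1C (-2.62) were negative. Of 29 mitosis genes tested, 11 had a positive interaction, 4 a negative one and 14 did not pass the test (14 and 4 adjusted over the list alone). Mitosis genes did not pass as a list (camera adjusted p = 0.0608). Its median was 0.86, and the members named by the rule, securin (PTTG1, -2.60) and survivin (BIRC5, -1.82), were negative. So were the proteasome subunit PSMB6 (-2.31), the secreted stress factor MANF (-1.91) and the glycolytic enzyme TPI1 (-1.64).

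Of 26 translation factors and other TOP mRNAs tested, 18 had a positive interaction, 0 a negative one and 8 did not pass the test (18 and 1 adjusted over the list alone). TOP mRNAs had a median of 1.57, with a camera adjusted p = 1.26e-10, and adjusted p = 0.238 with an estimated correlation. EIF3A (3.07), HNRNPA1 (2.73), EEF1G (2.99) and EIF4B (3.02) were positive. EEF2, the factor that moves the ribosome along the mRNA, fell in the light fraction (-1.23) and rose in the polysome fraction (1.43), an interaction of 2.66. EEF1A1, which brings aminoacyl-tRNA to the ribosome, did likewise (2.19). Of 38 ribosome biogenesis genes tested, 21 had a positive interaction, 2 a negative one and 15 did not pass the test (25 and 2 adjusted over the list alone). Biogenesis factors had a median of 1.15, with a camera adjusted p = 3.35e-10, and adjusted p = 0.155 with an estimated correlation. RRP12 (2.92), NOL6 (3.04) and NOC2L (2.61) were positive. Of 20 tRNA synthetase genes tested, 14 had a positive interaction, 0 a negative one and 6 did not pass the test (18 and 0 adjusted over the list alone). The synthetases had a median of 1.30, with a camera adjusted p = 7.48e-10, and adjusted p = 0.155 with an estimated correlation. QARS (2.62), AARS (2.48), VARS (2.39) and MARS (3.27) were positive. Of 79 cytosolic ribosomal protein genes tested, 10 had a positive interaction, 2 a negative one and 67 did not pass the test (9 and 2 adjusted over the list alone). Cytosolic ribosomal proteins had a median of 0.43, with a camera adjusted p = 0.0318, and adjusted p = 0.827 with an estimated correlation. RPL3 (2.53), RPL4 (2.06), RPS2 (2.41) and RPLP0 (1.56) were positive, RPS26 (-2.44) negative, and RPS6 (0.92, adjusted p = 0.135) not called.

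Of 26 ATF4 and integrated stress response targets tested, 11 had a positive interaction, 0 a negative one and 15 did not pass the test (12 and 1 adjusted over the list alone). The ATF4 targets had a median of 1.12, with a camera adjusted p = 0.00117, and adjusted p = 0.567 with an estimated correlation. PCK2 (1.92), PHGDH (1.56), DDIT3 (1.94) and ATF4 (1.74) were positive. The helicase subunits MCM3 (2.59) and MCM2 (2.23), the glycolytic ENO2 (2.40) and HK2 (2.54) and the lipid genes FASN (2.77), SREBF1 (2.21) and HADHA (2.25) were positive too. The chaperones HYOU1 (2.47) and HSPA5 (1.62), the snoRNA hosts SNHG5 (1.97) and SNHG16 (1.35), the survival factor MCL1 (1.49) and MYC (1.46) were as well. By edgeR ALB (0.80, adjusted p = 0.242) was not called. Secreted hepatocyte protein genes, which rose in both fractions, gave 8 positive and 7 negative interactions, and 13 of 28 did not pass the test. Their list did not pass either (camera adjusted p = 0.5255). Of 26 unfolded protein response genes 4 had a positive interaction, 5 a negative one and 17 did not pass, nor did the list (camera adjusted p = 0.607). Of the lists, 13 passed at the preset correlation and 0 with an estimated one.

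**Figure D3:**
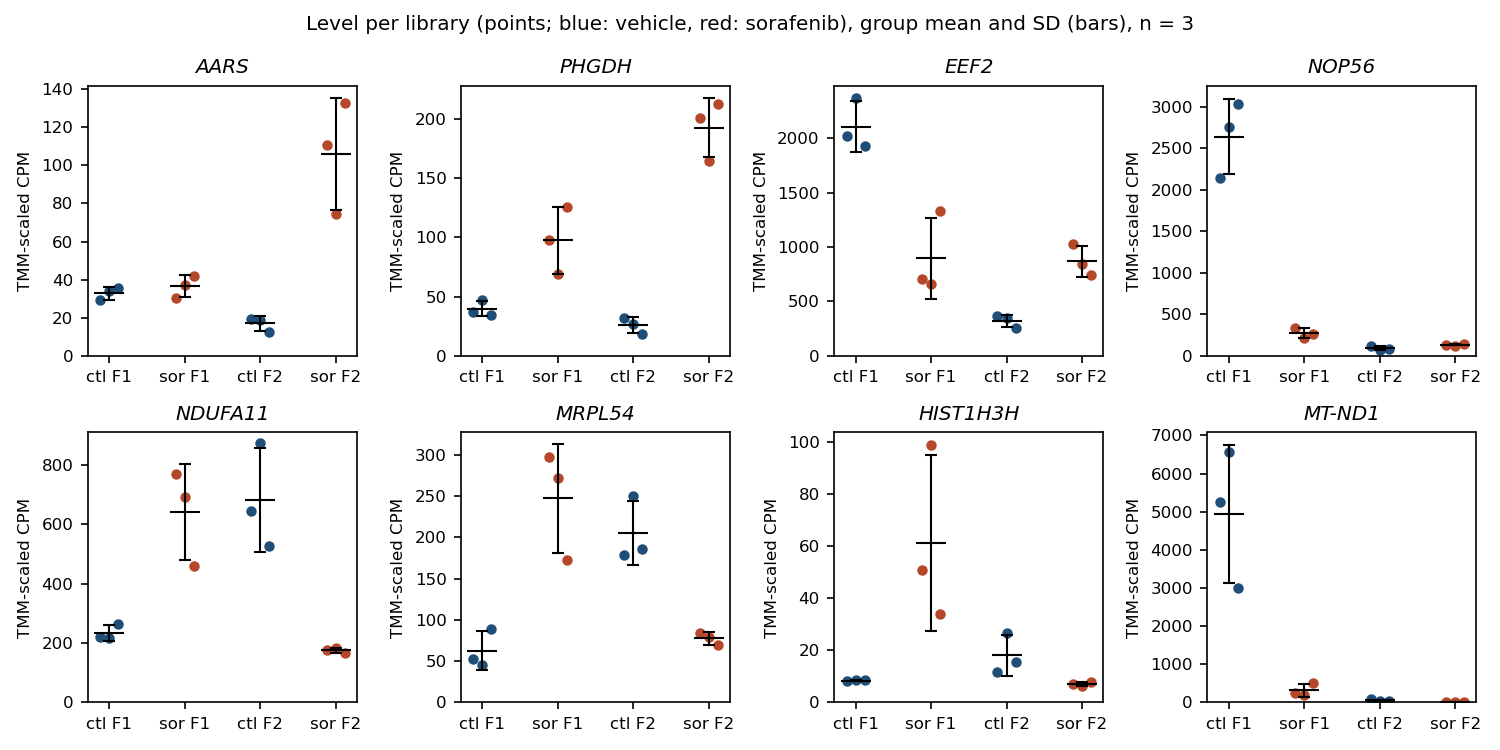
Each panel shows 1 gene in TMM-scaled CPM; points are libraries (blue, vehicle; red, sorafenib) and bars the group mean and SD, n = 3. After sorafenib NDUFA11 averages 640 in the light fraction and 175 in the polysome fraction.

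The fourth comparison set the polysome against the light fraction in vehicle cells. Genes for ribosomal proteins and translation factors were mostly lower in the polysome fraction, and those for respiratory chain subunits mostly higher. The ubiquitin-like modifier gene ISG15 was at 3.15 ± 0.27 (SE, n = 3 per group), the centromere gene CENPW at 2.91, NDUFC2 at 2.81 and BEX1 at 2.77. The small nuclear RNA RN7SK was at -6.56, the RNase P RNA RPPH1, for which sharing of reads with other genes was not tested, at -7.04, MT-TL1 at -6.83 and MT-ND1 at -6.45. By the edgeR test 2742 genes were higher and 2659 lower in the polysome fraction, 50.8% of the calls being higher. TMM within each fraction, which puts the fractions on no common scale, gave 5932 higher and 1129 lower (84%), library totals 7314 and 876 (89.3%), and upper-quartile factors 2153 and 3386 (38.9%), so values hold relative to the other genes only. The medians of all genes were -0.06, 0.58, 0.82 and -0.22 in that order. With both libraries of 1 culture left out, higher calls numbered 1505 without vehicle culture 2, and lower calls numbered 1530 without vehicle culture 2. With all libraries thinned to the smallest total, which left 7670 genes to test, 1001 were higher and 1220 lower.

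Of 79 cytosolic ribosomal protein genes tested, 1 was higher, 77 were lower and 1 did not pass the test (1 and 77 adjusted over the list alone). Cytosolic ribosomal proteins had a median of -2.37, with a camera adjusted p = 2.42e-45, and adjusted p = 0.197 with an estimated correlation. RPS4X (-3.36), RPLP0 (-3.28) and RPLP1 (-3.60) were lower. Of 26 translation factors and other TOP mRNAs tested, 0 were higher, 23 were lower and 3 did not pass the test (0 and 23 adjusted over the list alone). TOP mRNAs had a median of -2.19, with a camera adjusted p = 1.28e-19, and adjusted p = 0.196 with an estimated correlation. PABPC1 (-3.54), EIF3L (-3.02), TPT1 (-4.06), EEF1A1 (-2.99) and EEF2 (-2.71) were lower. So were the ferritin genes FTL (-5.42) and FTH1 (-4.88), which store iron, NOP56 (-4.83), the paraspeckle RNA NEAT1 (-3.33) and the synthetase genes QARS (-2.36) and MARS (-2.63). Of 77 nuclear-encoded respiratory chain and ATP synthase genes tested, 48 were higher, 3 were lower and 26 did not pass the test (52 and 3 adjusted over the list alone). Respiratory chain genes had a median of 0.92, with a camera adjusted p = 5.10e-13, and adjusted p = 0.31 with an estimated correlation. NDUFB6 (1.93) and NDUFB7 (2.01) were higher. Of 76 mitochondrial ribosomal protein genes tested, 44 were higher, 4 were lower and 28 did not pass the test (47 and 6 adjusted over the list alone). Mitochondrial ribosomal proteins had a median of 0.79, with a camera adjusted p = 8.70e-09, and adjusted p = 0.385 with an estimated correlation. MRPS34 (2.08) and MRPS14 (1.56) were higher. Of the lists, 12 passed at the preset correlation and 0 with an estimated one.

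The fifth comparison did the same in sorafenib cells. Genes for cytosolic ribosomal proteins, histones and mitochondrially encoded mRNAs were mostly lower in the polysome fraction. The collagen genes COL9A3 (3.66 ± 0.25, SE, n = 3 per group) and COL18A1 (2.77), EIF3A (2.79), the splicing factor gene SART1 (2.73) and the cohesin gene SMC1A (2.63) were higher. RMRP (-8.83), the RNA of the RNase MRP complex, RN7SK (-8.58) and the mitochondrial rRNA MT-RNR1 (-7.11) were lower. By the edgeR test 2002 genes were higher and 1855 lower, 51.9% of the calls being higher. TMM within each fraction gave 7041 higher and 740 lower (90.5%), library totals 5587 and 914 (85.9%) and upper-quartile factors 1189 and 2688 (30.7%), with medians of all genes at -0.00369, 0.79, 0.60 and -0.25. Higher calls numbered 3059 without vehicle light-fraction library 1, 3039 without vehicle light-fraction library 2, 3204 without vehicle light-fraction library 3, 3441 without sorafenib light-fraction library 3, lower calls 946 without sorafenib light-fraction library 1, and without both shallow libraries 1241 genes were higher and 920 lower. Vehicle libraries are not part of this contrast, but each fit filtered, scaled and estimated the spread anew, so the genes tested changed too (16260 without vehicle light-fraction library 1). With both libraries of 1 culture left out, higher calls numbered 3037 without vehicle culture 1, 3292 without vehicle culture 3 and 624 without sorafenib culture 1. Lower calls numbered 681 without sorafenib culture 1. Without a low-count filter 4719 of 45832 genes were higher and 2483 lower. The DESeq2 Wald test, also without that filter and with its own scaling, gave 2065 higher and 4441 lower calls among 45832 genes. With protein-coding genes only 1806 of 11828 were higher and 1094 lower. With all libraries thinned to the smallest total 629 of 7670 were higher and 983 lower.

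Of 79 cytosolic ribosomal protein genes tested, 0 were higher, 76 were lower and 3 did not pass the test (0 and 76 adjusted over the list alone). Cytosolic ribosomal proteins had a median of -1.87, with a camera adjusted p = 6.97e-51, and adjusted p = 0.115 with an estimated correlation. RPS29 (-2.71), RPL21 (-2.17) and RPL36 (-2.18) were lower. Of 26 translation factors and other TOP mRNAs tested, 2 were higher, 10 were lower and 14 did not pass the test (3 and 13 adjusted over the list alone). TOP mRNAs had a median of -0.63 (-0.91 to 0.16 over the scalings, so its sign depends on them), with a camera adjusted p = 0.00177, and adjusted p = 0.459 with an estimated correlation. Of 77 nuclear-encoded respiratory chain and ATP synthase genes tested, 4 were higher, 36 were lower and 37 did not pass the test (4 and 40 adjusted over the list alone). Respiratory chain genes had a median of -0.69 (-0.95 to 0.10 over the scalings, so its sign depends on them), with a camera adjusted p = 8.67e-07, and adjusted p = 0.379 with an estimated correlation. ATP5ME (-2.14) and NDUFB1 (-1.92) were lower. Of 36 replication-dependent histone genes tested, 0 were higher, 34 were lower and 2 did not pass the test (0 and 35 adjusted over the list alone). Histones had a median of -3.60, with a camera adjusted p = 2.96e-21, and adjusted p = 0.174 with an estimated correlation. Of 13 mitochondrially encoded mRNAs tested, 0 were higher, 12 were lower and 1 did not pass the test (0 and 13 adjusted over the list alone). These mitochondrial mRNAs had a median of -3.94, with a camera adjusted p = 4.86e-25, and adjusted p = 0.0403 with an estimated correlation. MT-CO2 (-5.00) and MT-ND4L (-4.62) were lower. Of the 18 lists that passed at the preset correlation this was the 1 that passed with an estimated one. The mitochondrial protease gene LONP1 (2.34), NOC2L (2.08), AARS (1.52), the mTORC1 inhibitor gene DDIT4 (1.58) and the amino acid transporter gene SLC7A5 (1.45) were higher in the polysome fraction.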

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

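The tests of the 3 patterns weighed here were chosen after the results were seen, and the counts over other splits were planned. The sorafenib effect differed between the fractions, by the interaction test, for 1921 genes upward and 1607 downward. Lists whose interaction passed had medians of translation factors and other TOP mRNAs (1.57), cytosolic aminoacyl-tRNA synthetases (1.30), ribosome biogenesis factors (1.15), ATF4 and integrated stress response targets (1.12), snoRNA host genes (1.11), glycolysis (0.81), fatty acid oxidation and PPARA targets (0.76), fatty acid synthesis (0.68), S phase and DNA replication (0.50) and cytosolic ribosomal proteins (0.43), and replication-dependent histones (-5.05), nuclear-encoded respiratory chain and ATP synthase (-1.41) and mitochondrial ribosomal proteins (-1.06). With an estimated correlation 0 of these 13 lists passed, and adjusted p = 0.155 to 0.827 over them. Named genes with a positive interaction were FTLP3 (4.38), NOP56 (3.79), DIAPH1 (3.65), COL18A1 (3.51), UNC45A (3.41), MARS (3.27), EIF3A (3.07), NOL6 (3.04), EIF4B (3.02), EEF1G (2.99), RRP12 (2.92), FASN (2.77), HNRNPA1 (2.73), EEF2 (2.66), QARS (2.62), NOC2L (2.61), MCM3 (2.59), HK2 (2.54), RPL3 (2.53), AARS (2.48), HYOU1 (2.47), RPS2 (2.41), ENO2 (2.40), VARS (2.39), HADHA (2.25), MCM2 (2.23), SREBF1 (2.21), EEF1A1 (2.19), RPL4 (2.06), SNHG5 (1.97), DDIT3 (1.94), PCK2 (1.92), ATF4 (1.74), HSPA5 (1.62), RPLP0 (1.56), PHGDH (1.56), MCL1 (1.49), MYC (1.46) and SNHG16 (1.35). Those with a negative one were HIST1H2BC (-6.29), PTMAP5 (-4.54), HIST1H3H (-4.07), MIR1244-1 (-3.77), MMAB (-3.64), PTMS (-3.62), NDUFA11 (-3.41), MRPL54 (-3.38), NDUFA13 (-3.37), NDUFA2 (-2.99), HIST1H1C (-2.62), PTTG1 (-2.60), MRPL36 (-2.45), RPS26 (-2.44), PSMB6 (-2.31), MANF (-1.91), BIRC5 (-1.82) and TPI1 (-1.64).

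The splits into 3 and 3 number 10, the real one included, too few for a share under 0.05. Each other split mixes the 2 real groups, so a real difference widens the spread within its arms and hinders gene calls. It also keeps part of the real contrast, so its counts of genes or lists do not measure chance. Some splits between fractions also put both fractions of a culture in the same arm. By edgeR the real split was the 1 of 10 that called genes in each of the 5 comparisons: 7436 on polysomes, 4400 in the light fraction, 3528 in the interaction, 5401 between fractions in vehicle and 3857 in sorafenib cells, with the highest other split at 0. Lists were called by other splits too. On polysomes 2 splits, the real one included, called as many as the real 20 lists, with the highest other at 21. In the light fraction it was 1 split, with 16 lists against 14, and in the interaction 2 splits, with 13 against 17. Between the fractions it was 7 splits in vehicle cells, with 12 against 15, and 1 in sorafenib cells, with 18 against 15. At an unadjusted p under 0.05 the other splits called at most 668 genes on polysomes, 1471 in the light fraction, 326 in the interaction, 1469 in vehicle and 1583 in sorafenib cells by edgeR; no other tool was run on them.

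Histones rose in the sorafenib light fraction by a median of 3.67. Some of these genes had few counts, such as HIST1H2BC (5.23) at a mean log2 CPM of 1.37, so the size of this median is uncertain. The better-counted HIST1H3H, HIST1H1C and HIST1H2AC (mean log2 CPM 3.95, 4.61 and 4.64) rose by 2.75, 2.57 and 1.95. HIST1H1E, at a mean of 3.10, rose by 4.23. Retention of RNA without a poly(A) tail could raise other such RNAs too. RN7SK, RMRP, RPPH1 and 3 RN7SL genes lay between 1.33 and 2.08 (median 1.92), against a median of -0.12 over all genes. Their median was below that of the histones by more than the pooled SD of 1.06, but this SD is a spread between genes. Such RNAs need not be retained alike, so retention stays open for all or part of the rise. Of these 6, chosen after the values were seen, RN7SL1 alone passed the edgeR test (adjusted p = 0.0472), so a shift of such RNAs is itself uncertain. RNA5SP202, a 5S rRNA pseudogene outside these 6, rose by 5.82 ± 1.3 (SE, edgeR adjusted p = 0.00271), above the histone median. Whether its reads come from 5S rRNA, which lacks a poly(A) tail, was not tested, and it is 1 gene. The 2 shallow libraries do not carry it alone, since without both the median was 3.01, resting on 1 library. An effect of sorafenib on histone mRNA stays open and was not tested apart from these.

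Respiratory chain and mitochondrial ribosomal protein mRNAs had a median interaction of -1.30. It was -1.44 without both shallow libraries and -1.24 with every library thinned to the smallest total, which argues against depth or these libraries as the whole cause. With the trend on gene span removed (99.3% of members had a span) the median interaction was -1.10. Cytosolic ribosomal protein genes, with shorter spans (median 5.01 kb against 9.3 kb), had a median of 0.43. Span is not transcript length, so these values do not decide on length. Over 11904 protein-coding genes, log2 change and span correlated at Spearman rho 0.25 on polysomes and 0.14 in the interaction. The polysome falls of these lists were not adjusted for span. Transcript length was not analysed here and stays open, as does a biological shift of these mRNAs.

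Mitochondrially encoded mRNAs fell in the light fraction by a median of 2.81 and in the polysome fraction by 1.94, which does not show that they sat on polysomes. Without both shallow libraries the light-fraction median was -2.15, so these libraries alone do not account for the fall. Fewer mitochondria in the lysate would lower mitochondrial rRNAs too, but the 2 of these lay on either side of 0, with MT-RNR1 at 0.76 and MT-RNR2 at -0.30 (median 0.23). The rRNAs are no clean measure if RNAs without a poly(A) tail are shifted there, which the 6 other such RNAs (1 of 6 passing the test) neither establish nor exclude. Less the median of those RNAs they stood at -1.69 and differed from the mRNAs by just under the joint SD of 1.12, so with 2 rRNAs and an uncertain offset a loss of mitochondria cannot be told apart from fewer transcripts.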

How the results depend on the processing

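Alternatives with TMM references, thinning or both shallow libraries left out were chosen after seeing the data, and the cause of a change was not tested unless stated. Over all alternatives, 9632 values of named genes kept direction and side of the threshold, 49 lost the call, 41 gained it and 57 turned sign, none of the last called in the main test. Single list calls held in 2229 and were lost in 141 cases. Counts that moved over 1.5 times, shares that moved by more than their SD between libraries and values that turned were as follows. Upper-quartile factors: sorafenib F2 vs F1 higher 1189. TMM within each fraction: polysome ATF4 0.0198, polysome RPLP0 0.12, polysome RPS6 0.00767, vehicle F2 vs F1 higher 5932, vehicle F2 vs F1 lower 1129, sorafenib F2 vs F1 higher 7041, sorafenib F2 vs F1 lower 740. Library total only: polysome RPLP0 0.0485, light higher 3650, light lower 1316, interaction higher 1210, vehicle F2 vs F1 higher 7314, vehicle F2 vs F1 lower 876, sorafenib F2 vs F1 higher 5587, sorafenib F2 vs F1 lower 914. DESeq2 Wald test, which also had no low-count filter (45832 genes) and its own scaling: light higher 2718, sorafenib F2 vs F1 lower 4441. No low-count filter (45832 genes tested): polysome lower 1663, polysome ATF4 0.20, polysome RPLP0 0.31, polysome RPS6 0.19, interaction lower 663, sorafenib F2 vs F1 higher 4719. Log2 fold change of at least 1: light higher 1133, vehicle F2 vs F1 higher 1609, sorafenib F2 vs F1 higher 1295. Only the groups compared: polysome ATF4 0.016, polysome RPLP0 0.12, polysome RPS6 0.00539. Protein-coding genes only (11828 tested): polysome lower 2742, polysome RPLP0 0.0055, light lower 1728, sorafenib F2 vs F1 lower 1094, ribosomal protein share sorafenib F1 minus vehicle F1 -13.8 points, ribosomal protein share vehicle F2 minus vehicle F1 -27.5 points, ribosomal protein share sorafenib F2 minus sorafenib F1 -17 points. The protein-coding total of this setting leaves out mitochondrial genes, so mitochondrial values are ratios to that total and not shares. In percent of it they were sorafenib F1 minus vehicle F1 -5.65, vehicle F2 minus vehicle F1 -7.66 and sorafenib F2 minus sorafenib F1 -2.39. The top-10 set here lacks MT-RNR2, MT-CO2 and MT-CO1, and gave vehicle F2 minus vehicle F1 -12.8 points and sorafenib F2 minus sorafenib F1 -6.38 points. Camera with an estimated correlation: polysome lists 0, light lists 0, interaction lists 0, vehicle F2 vs F1 lists 0, sorafenib F2 vs F1 lists 1. All libraries thinned to the smallest (7670 genes tested): polysome higher 1715, polysome lower 1715, light higher 844, light lower 988, light MYC -0.0364, interaction higher 839, interaction lower 895, vehicle F2 vs F1 higher 1001, vehicle F2 vs F1 lower 1220, sorafenib F2 vs F1 higher 629, sorafenib F2 vs F1 lower 983. Without both shallow sorafenib_F1 libraries: polysome ATF4 0.0599, polysome RPLP0 0.16, polysome RPS6 0.0485, light lower 1333, sorafenib F2 vs F1 higher 1241, sorafenib F2 vs F1 lower 920. With another TMM reference, signs on polysomes turned for sorafenib F1 library 3 RPLP0 0.0125, vehicle F2 library 1 RPLP0 0.0576, vehicle F2 library 2 ATF4 0.0332, RPLP0 0.14, RPS6 0.021, vehicle F2 library 3 ATF4 0.0437, RPLP0 0.15, RPS6 0.0327, sorafenib F2 library 1 ATF4 0.000313, RPLP0 0.10, sorafenib F2 library 2 ATF4 0.0198, RPLP0 0.12, RPS6 0.00767, sorafenib F2 library 3 RPLP0 0.10. Leaving out 1 library or culture gave ranges of polysome higher 2372 to 4232, polysome lower 2322 to 4059, light higher 909 to 2370, light lower 1412 to 2877, interaction higher 898 to 2836, interaction lower 701 to 1801, vehicle F2 vs F1 higher 1505 to 3116, vehicle F2 vs F1 lower 1530 to 3079, sorafenib F2 vs F1 higher 624 to 3441, sorafenib F2 vs F1 lower 681 to 2491, correlation 0.19 to 0.40, and, for values that turned, polysome ATF4 -0.32 to 0.18, polysome RPLP0 -0.26 to 0.36, polysome RPS6 -0.33 to 0.12, light DDIT3 -0.22 to 0.74, light MYC -0.50 to 0.45. With the replicate block by culture, 2215 interactions were positive and 1728 negative, and the block changed no other call printed. Numbers across treatments share only a number (deviations correlated at -0.01, -0.13, -0.14, -0.16, -0.05, 0.03); that replicate block gave 3134 rises and 4172 falls on polysomes, and MCL1 passed. The depth of the shallowest library, 511065 counts, limits what can be called among weakly expressed genes.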

Other observations

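Further gene lists were measured. They are given first for the polysome fraction. Of 16 cytosolic heat shock protein genes tested, 9 rose, 3 fell and 4 did not pass the test (9 and 3 adjusted over the list alone). Heat shock genes had a median of 0.86, with a camera adjusted p = 0.00708, and adjusted p = 0.268 with an estimated correlation. HSPA4L (2.31) and HSPA4 (2.26) were examples. In the light fraction 4 of the 16 rose, among them HSPA4 (1.17), HSPA8 (-2.10) fell and 11 did not pass the test. There the list did not pass (camera adjusted p = 0.482). Of 23 NRF2 and oxidative stress targets tested, 10 rose, 3 fell and 10 did not pass the test (12 and 3 adjusted over the list alone). NRF2 targets had a median of 0.59, with a camera adjusted p = 0.00708, and adjusted p = 0.327 with an estimated correlation. PGD (2.05), an enzyme of the pentose phosphate pathway, was an example. Of 28 autophagy and lysosome genes tested, 15 rose, 5 fell and 8 did not pass the test (15 and 5 adjusted over the list alone). Lysosomal genes had a median of 0.83, with a camera adjusted p = 0.00162, and adjusted p = 0.268 with an estimated correlation. The proton pump subunit ATP6V1H (2.46) and acid glucosidase (GAA, 1.94) were examples. Of 32 proteasome subunit genes tested, 12 rose, 4 fell and 16 did not pass the test (12 and 4 adjusted over the list alone). Proteasome genes had a median of 0.28, with a camera adjusted p = 0.0397, and adjusted p = 0.556 with an estimated correlation. PSMD2, of the regulatory particle, was at 1.50. Hypoxia genes (8 rose, 5 fell and 6 did not pass the test), p53 targets (6 rose, 5 fell and 10 did not pass the test) and cholesterol genes (7 rose, 2 fell and 15 did not pass the test) did not pass as lists (camera adjusted p = 0.053, 0.638 and 0.0995). The same held for mRNAs with upstream reading frames known to resist eIF2 phosphorylation (5 rose, 4 fell and 9 did not pass the test), eIF4E-sensitive mRNAs (4 rose, 3 fell and 5 did not pass the test) and liver transcription factors and metabolism (8 rose, 4 fell and 8 did not pass the test), at camera adjusted p = 0.638, 0.116 and 0.177. Blood cell markers, a check for other cells, gave 3 rose, 0 fell and 3 did not pass the test on polysomes and 1 rose, 0 fell and 5 did not pass the test in the light fraction.

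In the light fraction, 3 further lists gave these values. Of 8 metallothionein genes tested, 4 rose, 0 fell and 4 did not pass the test (6 and 1 adjusted over the list alone). Metallothioneins had a median of 1.11, with a camera adjusted p = 0.0116, and adjusted p = 0.544 with an estimated correlation. MT1X, a zinc-binding metallothionein, was at 2.37. Of 24 cholesterol synthesis and uptake genes tested, 4 rose, 1 fell and 19 did not pass the test (4 and 1 adjusted over the list alone). Cholesterol genes had a median of 0.26, with a camera adjusted p = 0.0352, and adjusted p = 0.681 with an estimated correlation. FDFT1 (1.82) and EBP (1.21), both enzymes of sterol synthesis, were examples. Of 29 mitosis genes tested, 9 rose, 0 fell and 20 did not pass the test (9 and 0 adjusted over the list alone). Mitosis genes had a median of 0.43, with a camera adjusted p = 1.94e-04, and adjusted p = 0.314 with an estimated correlation. Cyclin A2 (CCNA2, 1.65) and TPX2 (1.20) were examples. CCND1, a cyclin, was at 0.20 on polysomes (edgeR adjusted p = 0.597), and MCL1, a survival factor, at 0.69 (edgeR adjusted p = 0.0517).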
